A study of Mus musculus with 6 samples.

How the data were processed

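RNA given as that of the esophageal epithelium of adult mice was measured on 6 two-colour expression arrays. 3 arrays were labelled wild type and 3 were labelled as knockouts of Pax9, a paired-box transcription factor, in which a keratin 5 Cre driver recombines a floxed Pax9 allele. Per the labels, each array carried esophagus RNA in Cy5 and a reference RNA pooled from cultured mouse cell lines in Cy3. The reference was common to all arrays and no dyes were swapped. The channels bore this out: Krt4, Krt13 and Sprr3 were far brighter in Cy5 than in Cy3 on all 6 arrays, and Afp was bright only in Cy3. The labels call the samples of a group biological replicates, with no further word on the animals, so p-values measure the spread between these samples. The arrays of each group shared a slide, so no p-value measures the spread between slides.

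The deposited scanner files hold linear intensity values for 45018 spots per array, made with Agilent Feature Extraction 10.7.3.1 on array design 014868, per the file headers. The submitters' processing notes name version 9.1 of that program, so the version differs between those sources. The files also carry a log10 ratio of Cy5 over Cy3, deposited by the authors after the program's own background subtraction and dye normalization. The series matrix, also deposited, holds log2 values. Set against the scanner log2 ratio of the same array, its columns had correlations of -0.993 to -0.996 over probes and a slope near -1. Its column medians lay between -0.02 and 0.02. These values are therefore log2 of Cy3 over Cy5, opposite in sign to the sample over reference ratio used here, and how they were centred is not given in the sources used here.

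From the intensity columns, background was corrected with normexp at an offset of 50, and each array was normalized by loess with control spots at weight 0. Control spots were then left out, and spots flagged as outliers, 55 to 164 per array, were set to missing. No spot was saturated. Spots of a probe were averaged, giving 41174 probes. A probe was tested if its Cy5 signal was well above background on all 3 arrays of at least 1 group, which held for 30505 probes. Probe names were updated through a table of RefSeq genes of assembly GRCm38.p6, used for names only. 26918 probes matched by accession, 5899 by name or synonym, and 8357 kept the name in the files. Probe positions are those of the files, on mouse build mm9. A gene with several tested probes was represented by the probe with the highest mean intensity, giving 20820 genes, of which 16853 have a RefSeq symbol. Of the 242 genes past the threshold with several tested probes, 3 had probes past it in opposite directions.

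The difference of the arrays labelled knockout minus those labelled wild type was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), without a covariate. P-values were adjusted by the Benjamini-Hochberg method over tested probes, with a threshold of 0.05. Errors are the SD over 3 arrays for group means and the moderated SE for differences. The number of arrays limits the precision. An exact permutation test of 3 against 3 arrays cannot go below p = 0.1. A probe not well above background on any array of a group has only a bound there, given as "at least N-fold". That bound is the bright group's mean against, on each dim array, the higher of the probe's own signal and the lowest signal among probes well above background, in Cy5 after loess and Aquantile, and open to dye bias without a dye swap. Where the fold in the main fit or an alternative was smaller than this, the smallest over all settings run is printed, and no fold where the sign turned in a setting. None of these folds is a confidence limit, and a gene that missed the threshold has no shown minimum change.

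31 gene lists fixed before the data were examined were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The genes named here follow a rule fixed at the same time: Pax9, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with fully separated groups and 1 symbol, 11 squamous epithelial genes whatever their result (Krt5, Krt14, Krt4, Krt13, Krt1, Krt10, Ivl, Trp63, Sox2, Klf4 and Mki67), the 3 members with the smallest p in each list, and sex-linked genes. Some genes that the rule takes are not reported here. Others are said to have been chosen after their values were seen.

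The procedure was tested on simulated data for this comparison, over 20811 genes with 200 seeded changes. A change of size 1 on the log2 scale was recovered in 25% of 100 genes and a change of size 2 in 70% of 100, with 2 false calls. No list was called without a shift. Noise was drawn independently for each gene, so the simulation holds no correlation between genes and no slide effect. It cannot show how often genes or lists are called falsely in the real data.

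All arrays labelled wild type lay on slide 1 with scan 1, and all those labelled knockout on slide 2 with scan 2, so batch and group cannot be told apart. Replicate numbers are shared between the groups. Deviations from the group means correlated at 0.17, 0.51 and 0.34 over genes for numbers 1, 2 and 3, all above 0.1, so the numbers pair the arrays by the rule set beforehand. Pairs of different numbers lay between -0.49 and 0.16, the highest being wild type 1 with knockout 3, so the pairing is not clear for number 1. What the numbers stand for is not given in the labels. On each slide numbers 1, 2 and 3 lay at positions 2, 3 and 4. A replicate block therefore takes out position as well, and pairing of samples and position cannot be told apart. Alternatives covered background correction, the deposited log ratios, the normalization, Cy5 alone, the filter on dim probes, eBayes with a trend, array weights, a replicate block, averaging of probes and leaving out each array.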

Results

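Expression was measured in the esophageal epithelium of adult C57BL/6J mice on 6 arrays, 3 labelled wild type and 3 labelled Pax9 knockout. The comparison asks which genes differ in the esophageal lining when Pax9 is deleted with a Cre driver active in keratin 5 cells. The muscle genes Acta1 and Ckm, named after their values were seen, had background-subtracted Cy5 signals of 8528 to 354828 and 754 to 70537. The RNA was thus not of epithelium alone. Cy5 signal was well above background for 67.3% to 77.3% of probes on the arrays labelled wild type and for 71.8% to 76.1% on those labelled knockout. The median Cy5 signal was 109, 124 and 218 on replicates 1, 2 and 3 labelled wild type and 153, 192 and 181 on those labelled knockout. Values are log2 ratios of sample over reference, and differences are the arrays labelled knockout minus those labelled wild type. The deposited matrix carries the opposite sign.

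Pax9 itself was not lower on the arrays labelled knockout. Its probe on chromosome 12 (57811169 to 57811228, mm9) read 6.04 ± 0.30 (SD, n = 3) on the arrays labelled wild type and 6.77 ± 0.05 (SD, n = 3) on those labelled knockout. The difference of 0.73 (SE 0.18) missed the threshold in limma (adjusted p = 0.071), and with Cy5 alone it was 1.09 (adjusted p = 0.0094). Background-subtracted Cy5 signals were 4414, 4716 and 8919 against 17209, 18936 and 19080. The labels do not say which exons are floxed, and the probe was not placed on the transcript, so a probe outside the deleted part would check nothing. Because the target gene goes against the labels, groups are called by their labels throughout, and each direction below rests on them.

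Krt1, Wnt3 and Gata3 were among the 10 largest falls on the arrays labelled knockout. Krt1, the keratin that pairs with Krt10 in the upper layers of the epidermis, fell by 5.28 (SE 0.54, adjusted p = 0.0088), from 7.65 ± 0.39 to 2.37 ± 1.16 (SD, n = 3 each). The difference was -2.66 as a mean over its probes and -9.08 with Cy5 alone. Its probe lies on chromosome 15 at 101676107 to 101676166 (mm9). The probe of Wnt3, a secreted Wnt ligand, was not well above background on the arrays labelled knockout, where it was at least 12.9-fold lower (adjusted p = 0.0012), and Gata3, a zinc-finger transcription factor, fell by 3.54 (SE 0.50, adjusted p = 0.02). Among the largest rises were Ada, adenosine deaminase, by 4.13 (SE 0.21, adjusted p = 0.0014), and Krt35, a hair keratin, by 3.74 (SE 0.28, adjusted p = 0.0038).

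**Figure D1:**
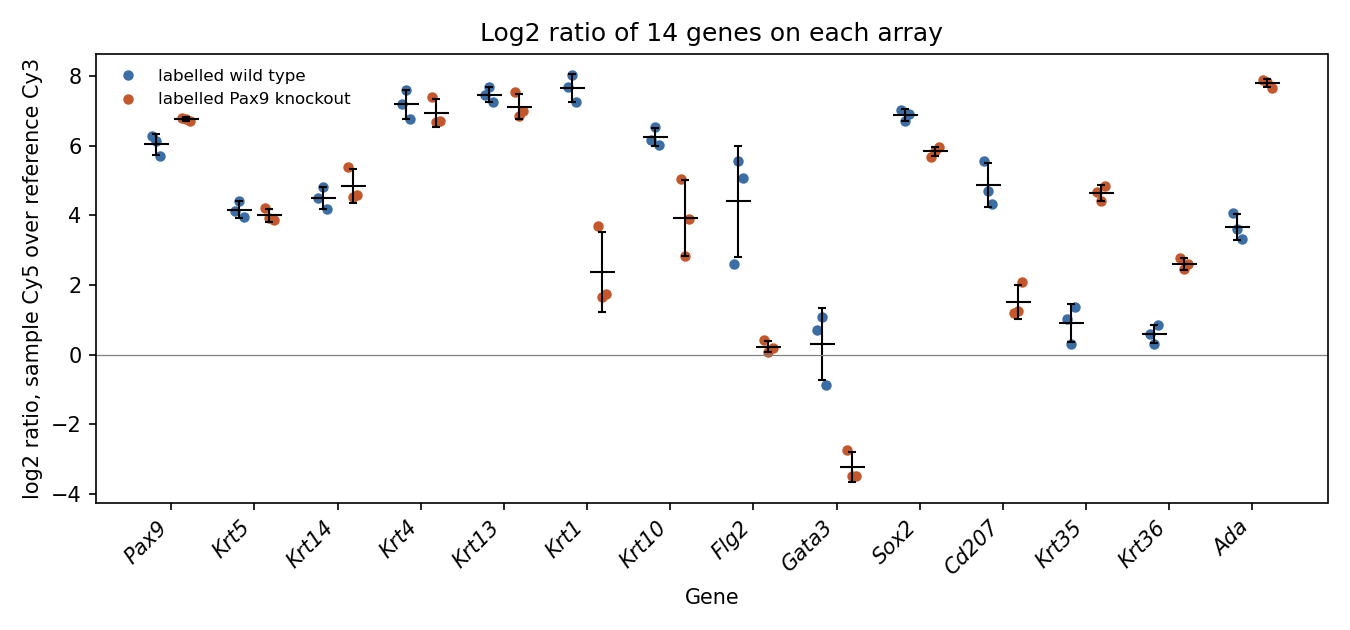
Log2 ratio of sample Cy5 over reference Cy3 for 14 genes on each of the 6 arrays, with blue points for arrays labelled wild type, orange points for arrays labelled knockout, and black bars for the group mean ± SD. Krt1, Flg2, Gata3 and Cd207 sat lower on all arrays labelled knockout, Krt35, Krt36 and Ada sat higher, and Krt5, Krt14, Krt4 and Krt13 overlapped between groups (the Krt14 difference reads -1.44 with Cy5 alone).

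In all, 1007 of 20820 genes passed the threshold, 590 higher and 417 lower on the arrays labelled knockout, and 605 of them changed at least 2-fold (364 higher, 241 lower). At an unadjusted p under 0.05 there were 5152 genes. With the replicate number as a block the counts were 1707 and 953. Over all genes the groups were fully separated in 32.2%, where chance gives 10%. Of the 1007, 309 also passed in the same direction with the deposited log ratio and 308 with the matrix values. In each of these 10 turned in sign. With median centring 115 passed in the same direction and 19 turned. With Cy5 alone, which calls 6005 genes and shares its data with the ratio, 986 passed in the same direction and 2 turned. The count fell to 57 without wild type replicate 1, 151 without wild type replicate 2, 267 without knockout replicate 1 and 34 without knockout replicate 3, and to 120 with median centring in place of loess. Each group occupied its own slide and scan, so slide and genotype label cannot be told apart.

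Among the 10 largest falls, Idi2, an isopentenyl diphosphate isomerase, fell by 5.95, as did Spink12, a Kazal-type protease inhibitor. 9130409I23Rik was not well above background on the arrays labelled knockout and was at least 14.4-fold lower there. Wfdc21, a small secreted WAP-domain protein, fell by 4.79 and Ankk1 by 3.40. Over single leave-outs Wfdc21 lay between -5.97 and -3.94 (adjusted p up to 0.14), and the adjusted p of Ankk1 reached 0.072. Flg2, a filaggrin-family protein of the cornified layer, was at least 10.3-fold lower, and Sprr2d, a small proline-rich envelope protein, fell by 3.76. The adjusted p of these genes ranged from 0.00079 for 9130409I23Rik to 0.044 for Sprr2d. Wfdc21, Flg2 and Sprr2d lost the threshold with median centring, and Spink12 (-3.13), Sprr2d (-0.95) and Wfdc21 (-4.12) with the deposited log ratio. Krt1 did not pass without wild type replicate 1 (adjusted p = 0.056) or knockout replicate 3 (adjusted p = 0.054), nor Gata3 without wild type replicate 1 or 2 or knockout replicate 1 or 3 (adjusted p up to 0.10).

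Among the 10 largest rises were Dynap (5.34), Emb (3.60), Lpcat2b (3.50), Dnajc6, which encodes the clathrin-uncoating factor auxilin (3.96), and Olfr266, an olfactory receptor gene (3.52). So were the cytochromes Cyp2a5 (4.24) and Cyp2c65 (3.99) and the carboxylesterase Ces1b (3.98), enzymes known from xenobiotic metabolism. Their adjusted p ranged from 0.0019 for Dnajc6 to 0.012 for Cyp2a5. With the deposited log ratio Ces1b read 0.47, Cyp2a5 1.66 and Lpcat2b 1.43, none past the threshold. Ces1b, Cyp2a5, Lpcat2b and Olfr266 also lost it without wild type replicate 1 or without knockout replicate 3, at adjusted p up to 0.065, 0.072, 0.072 and 0.054.

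Of the 54 named genes past the threshold that were followed through the alternatives, 5 passed in every setting that gave them a value: Idi2, Wnt3, Ada, Dnajc6 and 9130409I23Rik. Leaving out at least 1 single array ended the call of 44 of them, median centring that of 32 and the deposited log ratio that of 25.

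Keratins of the basal and the normal esophageal upper layers did not pass the test. Differences were -0.16 for Krt5, 0.34 for Krt14, -0.26 for Krt4 and -0.34 for Krt13, with adjusted p of 0.65, 0.51, 0.62 and 0.40. With Cy5 alone Krt14 passed in the opposite direction, at -1.44 (adjusted p = 0.0041), and Krt5, Krt4 and Krt13 read 0.23, 0.14 and 0.04. Krt10 differed by -2.31 (SE 0.50, adjusted p = 0.053), by -5.93 with Cy5 alone (adjusted p = 0.0041), and with a replicate block its adjusted p was 0.032. Ivl, a cornified envelope precursor, differed by -1.08 (adjusted p = 0.30). Sox2, a transcription factor of the foregut epithelium, fell by 1.04 (SE 0.16, adjusted p = 0.023), but the difference was -0.06 in the deposited log ratio. Trp63 (0.28), Klf4 (-0.26) and Mki67 (0.23) did not pass.

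Of 31 gene lists, 9 passed camera with the preset correlation and 0 with an estimated one. Fry's directional test called 0 (lowest adjusted p = 0.14) and its mixed test, for changes in either direction, called 20. With Cy5 alone camera called 1, epidermal cornification (adjusted p = 0.025). All 9 lost the call without at least 1 single array. In 6 of the 10 splits of the 6 arrays into 3 and 3, the real one included, at least 9 lists passed camera. The count of lists thus does not set the real groups apart from other splits.

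The epidermal cornification list, skin-type barrier genes, lay lower on the arrays labelled knockout. Of 32 tested members, 0 rose, 2 fell (Krt1 and Flg2) and 30 did not pass, and 3 fell when adjusted over the list alone (camera adjusted p = 0.0027, and adjusted p = 0.86 with an estimated correlation). The list lost its call without replicate 2 in both groups (adjusted p = 0.44). Barrier lipid genes also lay lower, with 0 up and 2 down of 29: the lipase Lipn was at least 1.69-fold lower and the fatty acid desaturase Scd1 fell by 1.03. Adjusted over the list alone the count was 2 (camera adjusted p = 0.004, and adjusted p = 0.80 with an estimated correlation).

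Transcription factors of stratified epithelium had 0 members up and 2 down of 28, Gata3 and the homeobox gene Dlx3, which fell by 1.04 (-0.37 and not past the test in the deposited log ratio), and 5 down adjusted over the list alone. Camera gave an adjusted p of 0.016, and an adjusted p = 0.86 with an estimated correlation. Ovol2 differed by -0.66 (adjusted p = 0.053), but by 0.25 with Cy5 alone, where the Cy3 reference differed by 1.17. The esophageal squamous differentiation list had 0 up and 3 down of 38 (also 3 adjusted over the list alone): Sprr2d, the serine protease Tmprss11e, which fell by 1.91, and Sprr4, which fell by 1.26. With the deposited log ratio Tmprss11e read -0.67 and Sprr4 -0.96, neither past the test. Camera gave an adjusted p of 0.069, and 0.044 with a replicate block, but an adjusted p = 0.86 with an estimated correlation. Of 24 wound keratins and alarmins 1 fell, the stefin Stfa2, by 2.74 (2 up and 2 down adjusted over the list alone, camera adjusted p = 0.27), but it read 0.078 in the deposited log ratio. Krt6b differed by -2.02 (adjusted p = 0.067) and the defensin Defb3 by 1.58 (adjusted p = 0.059, and 0.013 with a replicate block).

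Hard keratins, which build hair, nails and tongue papillae, lay higher. Of 13 tested members 4 rose and 0 fell: Krt35, Krt32 by 2.71, Krt36 by 2.01, and Krt33a, which was at least 1.88-fold higher. Krt32 is named after its value was seen. Adjusted over the list alone, 6 rose and 1 fell (camera adjusted p = 0.032, and adjusted p = 0.80 with an estimated correlation). The Krt35 probe lies on chromosome 11 at 99953539 to 99953598 (mm9). The camera call was lost with median centring (adjusted p = 0.31), and without replicate 2 in both groups (adjusted p = 0.067).

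**Figure D2:**
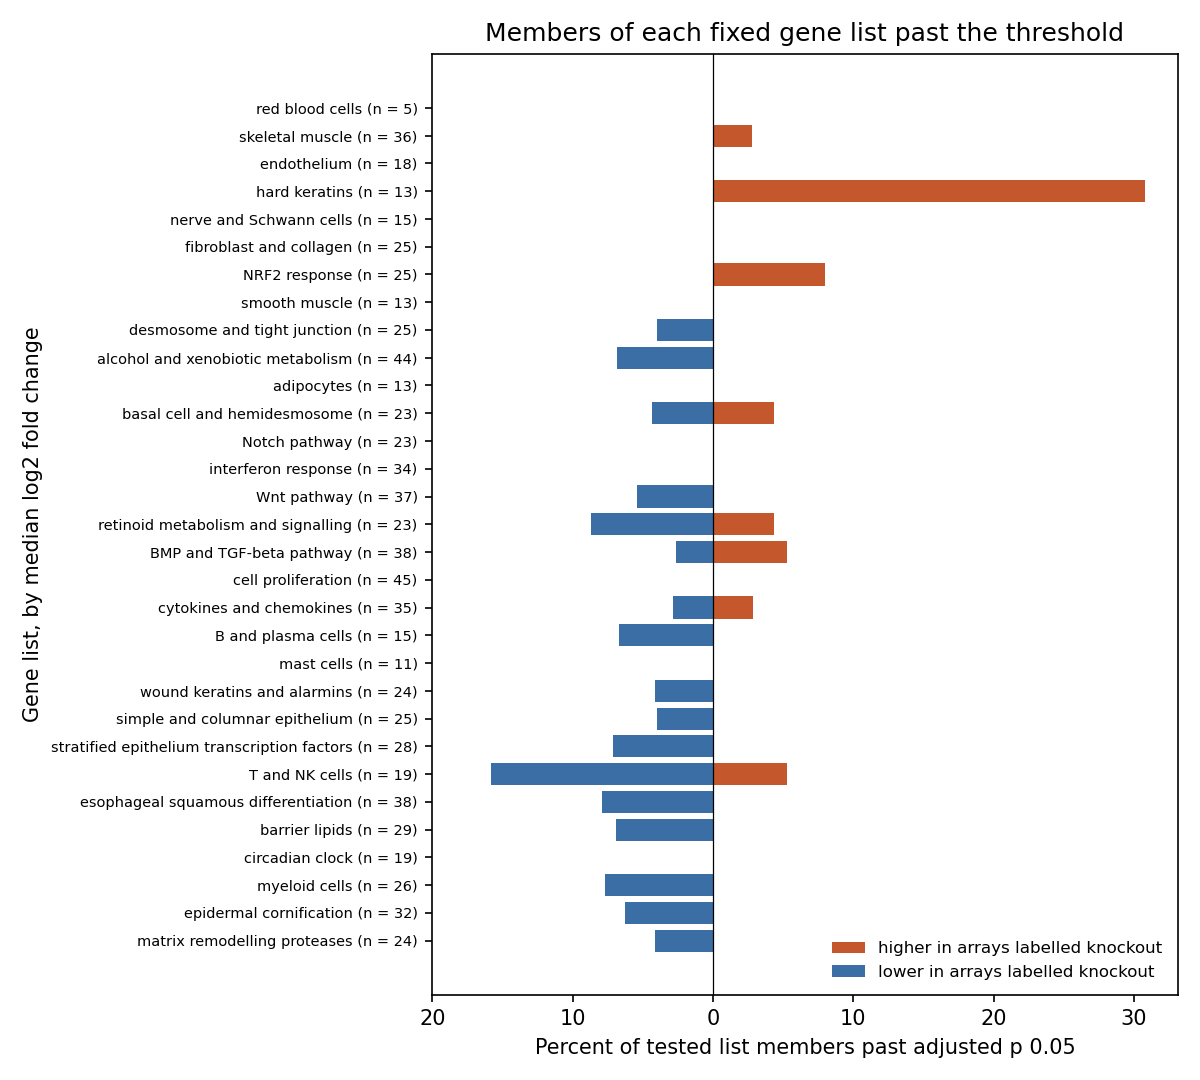
Percent of tested members of each of 31 gene lists past the adjusted threshold, with orange bars to the right for members higher and blue bars to the left for members lower on the arrays labelled knockout. Lists are ordered by median log2 difference and n is the number of tested members. Hard keratins had 4 of 13 members higher, and T and NK cells had 3 of 19 lower.

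Basal cell and hemidesmosome genes had 1 member up and 1 down of 23 (the same when adjusted over the list alone): the laminin chain Lamb3 rose by 0.92 and Sox2 fell (camera adjusted p = 0.96). Of 25 desmosome and tight junction genes 1 fell, the claudin Cldn1, by 1.67 (1 adjusted over the list alone, camera adjusted p = 0.56). Jup differed by -0.57 and Cldn3 by 0.51, neither past the test. No cell proliferation gene of 45 passed, nor any adjusted over the list alone (camera adjusted p = 0.62). In limma the smallest p in that list was for Melk (0.98, adjusted p = 0.05, not under it, but 0.027 with a replicate block), with Cdk1 at -0.78 and Aurka at -0.79. Of 25 simple and columnar epithelium genes 1 fell, Foxa3, which was at least 2.12-fold lower, and 5 fell adjusted over the list alone (camera adjusted p = 0.088). Hnf4a (-0.66) and Krt19 (-0.75) did not pass.

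The detoxification lists had members past the test in both directions. Of 44 alcohol and xenobiotic metabolism genes 3 fell, the epoxide hydrolase Ephx2 by 2.14 and the glutathione transferases Gstm5 by 1.67 and Gsta3 by 1.36 (3 up and 3 down adjusted over the list alone, camera adjusted p = 0.85). In the NRF2 response, an antioxidant program, 2 of 25 rose and 0 fell: the quinone reductase Nqo1 by 1.38 and the peroxiredoxin Prdx6 by 0.90 (4 up adjusted over the list alone, camera adjusted p = 0.13). Ftl1 differed by 0.55 (adjusted p = 0.062). In retinoid metabolism and signalling, 1 rose and 2 fell of 23, the same when adjusted over the list alone. The retinoic acid binding protein Crabp2 rose by 1.29 (0.57 and not past the test in the deposited log ratio), the retinol dehydrogenase Rdh9 fell by 2.48, and Rdh1 was at least 2.22-fold lower (camera adjusted p = 0.61).

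In the Wnt pathway list 2 of 37 fell, Wnt3 and Wnt9a (by 0.65, adjusted p = 0.06 with a replicate block). Wnt5b differed by 0.77 without passing, but passed with a replicate block. Adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.62, with a mean of -0.14 and a median of 0.02). The BMP and TGF-beta pathway had 2 up and 1 down of 38: Bmp3 rose by 2.46 (1.01 and not past the test in the deposited log ratio), Tgfb3 rose by 1.00 and Bmp4 fell by 1.24 (3 up and 1 down adjusted over the list alone, camera adjusted p = 0.96, with a mean of 0.06 and a median of -0.04). No Notch pathway gene of 23 passed, nor any adjusted over the list alone (camera adjusted p = 0.96), and Dll1 (0.70), Dll3 and Jag1 (-0.53) had the smallest p. Dll3 was not well above background on the arrays labelled knockout and did not pass in limma (adjusted p = 0.08). Its smallest fold over the settings was 1.26, lower on those arrays. Of 24 matrix remodelling proteases 1 fell, the cathepsin Ctsl, by 1.85, and 5 fell adjusted over the list alone. Camera gave an adjusted p of 0.025, and an adjusted p = 0.82 with an estimated correlation. Plaur (-0.80) did not pass, nor did Mmp10, not well above background on the arrays labelled knockout (smallest fold over the settings 1.35, lower there).

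No circadian clock gene of 19 passed, nor any adjusted over the list alone, with Per2 at -1.65, Ciart at -1.21 (adjusted p = 0.029 with a replicate block) and Bhlhe41 at -0.72. The list's camera adjusted p was 0.047, and the adjusted p = 0.80 with an estimated correlation. Of 35 cytokines and chemokines 1 rose, Cxcl12 by 0.74, and 1 fell, the prostaglandin synthase Ptgs2 by 1.51 (2 up and 4 down adjusted over the list alone, camera adjusted p = 0.26). Ccl17 differed by -2.09 (adjusted p = 0.052) and passed with a replicate block. The interferon response had 0 of 34 past the test and none adjusted over the list alone (camera adjusted p = 0.96, direction down against a mean and median of 0.04), with Ifi35 at 0.84 (adjusted p = 0.049 with a replicate block) and Rsad2 at -0.63. Mx1 was not well above background on the arrays labelled wild type (adjusted p = 0.074).

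None of the 4 immune cell lists passed camera. Among 26 myeloid genes 2 fell (2 adjusted over the list alone): Cd207, the langerin of Langerhans cells, fell by 3.35 (SE 0.37, adjusted p = 0.01), and the integrin Itgax fell by 1.63 (-0.73 and not past the test as a mean over its probes). With the deposited log ratio the Cd207 difference was -1.46 and did not pass. Camera gave an adjusted p of 0.069, and 0.0087 with a replicate block, but an adjusted p = 0.87 with an estimated correlation and 0.65 without knockout replicate 2. Aif1 differed by -0.78 and passed with a replicate block. Of 19 T and NK cell genes 1 rose and 3 fell: Cd5 rose by 1.93, Zap70 fell by 1.09, Cd3d by 1.00 and Cd3g, named after its value was seen, by 0.94. Adjusted over the list alone 2 rose and 5 fell (camera adjusted p = 0.22). Of 15 B and plasma cell genes 1 fell, Pou2af1, by 1.35 (1 adjusted over the list alone, camera adjusted p = 0.18), with Cd79a at -0.29. No mast cell gene of 11 passed, nor any adjusted over the list alone (camera adjusted p = 0.69), with Fcer1a at 0.64, Gata2 at -0.57 and Ms4a2 not well above background on the arrays labelled wild type.

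Skeletal muscle markers lay higher on the arrays labelled knockout, with list means of 3.36, 4.60 and 3.36 on replicates 1, 2 and 3 against 2.08, 4.12 and 2.10. Of 36 members 1 rose, Myh2, a fast myosin heavy chain, by 1.63 (1 adjusted over the list alone). Within each group Myh2 read lowest on replicate 2, where the list mean was highest, so it did not follow the order of the list. It passed in 10 of 21 alternative settings, with an adjusted p in limma of up to 0.57. Tnnt1 differed by 1.68 and Myh7 by -0.93, and both passed with a replicate block. Camera gave an adjusted p of 0.016, and an adjusted p = 0.87 with an estimated correlation. Without knockout replicate 2 the mean difference of the list was 0.59 and the call was lost (adjusted p = 0.17). Red blood cell markers had means of 4.41, 3.03 and 3.62 against 2.66, 2.29 and 1.47. No member of 5 passed, but 4 rose adjusted over the list alone, with Hbb-bt at 2.36, Hba-a1 at 2.03 and Alas2 at 1.47. Over single leave-outs of the same probe Hbb-bt lay between 1.58 and 2.95 and Hba-a1 between 1.44 and 2.62, and with a replicate block Hba-a1 (adjusted p = 0.046) and Alas2 (adjusted p = 0.034) passed. The list passed camera (camera adjusted p = 0.037, and adjusted p = 0.80 with an estimated correlation). Among 18 endothelial genes none passed, nor any adjusted over the list alone, with Cldn5 at 1.06, Robo4 at 0.84 and Tek at 0.56. Cldn5 differed by 0.05 with Cy5 alone (adjusted p = 0.89) and by -1.05 in the Cy3 reference. With a replicate block Cldn5 (adjusted p = 0.035) and Robo4 (adjusted p = 0.041) passed. The list passed camera (camera adjusted p = 0.025, and adjusted p = 0.80 with an estimated correlation).

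**Figure D3:**
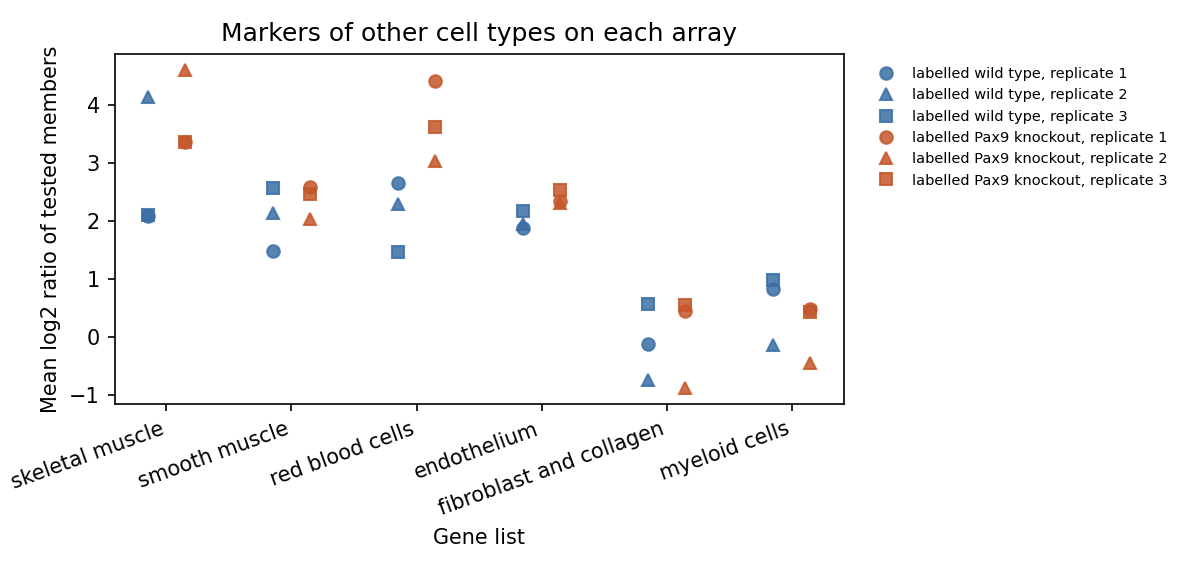
Mean log2 ratio of sample over reference over the tested members of 6 cell type lists on each array, with blue for arrays labelled wild type, orange for arrays labelled knockout, and the marker shape for the replicate number. Skeletal muscle was highest on replicate 2 of both groups (4.12 and 4.60), and red blood cell markers were higher on all arrays labelled knockout.

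The remaining lists had no member past the test, though with a replicate block Hspb6 (adjusted p = 0.014), Mfap5 (adjusted p = 0.015) and Ngfr (adjusted p = 0.02) passed. Smooth muscle (13 genes, camera adjusted p = 0.52) had Hspb6 at 1.5 and Lmod1 at 0.84. Fibroblast and collagen genes (25, camera adjusted p = 0.96) had Mfap5 at 1.26, Twist1 at -0.66 and Lox at 0.46. Nerve and Schwann cell genes (15, camera adjusted p = 0.18) had Ngfr at 1.05 and Prph at 0.50. Adipocyte genes (13, camera adjusted p = 0.96, direction down against a mean of 0.17 and a median of 0.07) had Lipe at -0.79, Plin1 at 0.65 and Pnpla2 at -0.65. Adjusted over the list alone, 1 adipocyte gene rose and none of the other 3 lists had a member past the test.

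Sex-linked genes matched between the groups by replicate number. Eif2s3y, on the Y chromosome, had log2 Cy5 signals of 11.50, 11.08 and 6.10 on replicates 1, 2 and 3 labelled wild type and 11.56, 11.56 and 6.13 on those labelled knockout. Ddx3y, Kdm5d and 2 of 3 Uty probes likewise read lowest on replicate 3 of both groups. Xist read highest on replicate 3 of both groups, at 12.70 and 11.88 for 1 of its probes. By these signals numbers 1 and 2 read as male and number 3 as female in both groups. With sex as a block 719 genes passed, and 661 of the 1007 genes passed in the same direction.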

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

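All tests in this part were chosen after the result was seen. The Cy3 channel held the same reference RNA on every array, yet 16524 of 31564 probes differed between the slides past the adjusted threshold, 997 of them at least 2-fold, a signal in data that the comparison uses only as a divisor. Of the probes tested in both, the ratio called 1127, 635 of them at least 2-fold. Ratio and Cy3 changes correlated at 0.47 over probes, so dividing did not leave the ratio unrelated to the Cy3 change. An effect of slide or scan shared by both dyes may account for part of the Cy3 change, since Cy3 and Cy5 changes correlated at 0.79 over 15618 probes that were brighter in Cy3. Cy5 light read in Cy3 may add to it: for probes far brighter in Cy5 on knockout replicate 2 than on the rest of its slide, Cy3 rose by a median of 2.04% of the Cy5 rise (quartiles 1.24 and 3.22, 97 probes). For Krt14 the Cy3 difference was 13.9% of the Cy5 difference, far above the upper quartile of 3.22, which argues against such light as its cause. Slide and group coincide, so how much of either dye's change belongs to the slide stays open, and no biological explanation was tested.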

How the results depend on the processing

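The leave-outs of both arrays numbered 2 or 3 and the sex block were chosen after seeing the data, and the other settings before the data were examined. The 1007 changed genes became 571 with the deposited log ratio, 561 with the matrix values (sign turned), 120 with median centring, which moved the median of all genes to 0.11, 6005 with Cy5 alone, 567 with both channels above background (17041 genes tested), 2469 with array weights and 1707 with the replicate block. The 605 genes changed at least 2-fold became 120 with median centring, 2142 with Cy5 alone, 919 with array weights and 953 with the replicate block. The 9 lists became 1 with Cy5 alone and 0 with an estimated correlation. Leaving out arrays gave 17 to 827 changed genes, 17 to 659 changed at least 2-fold and 2 to 11 lists. The lowest single leave-out was 34, without knockout replicate 3. Lists fell to 4 without wild type replicate 2 or knockout replicate 2. The Pax9 difference kept its sign in every setting run and passed with Cy5 alone (1.09) and array weights (0.63), and lay between 0.56 and 0.85 without single arrays. Stfa2 turned to 0.078 with the deposited log ratio and to 0.078 with the matrix values, and Krt14 to -1.44 with Cy5 alone. Apart from the leave-outs and settings that test fewer genes, the cause was not tested. Over all settings, named genes kept their side of the threshold in 1888 cases, passed newly in 132, lost it in 347 and reversed in 3, and for lists these were 598, 22, 61 and none. With the replicate block Wnt9a lost the threshold (adjusted p = 0.06), and besides Krt10 these named genes gained it, at adjusted p of 0.013 (Defb3) to 0.049 (Ifi35): Aif1, Alas2, Ccl17, Ciart, Cldn5, Defb3, Hba-a1, Hspb6, Ifi35, Melk, Mfap5, Myh7, Ngfr, Robo4, Soat1, Tnnt1 and Wnt5b. The block changed no other call of a named gene, and among lists only those of esophageal squamous differentiation and myeloid cells. Aquantile leaves log ratios unchanged by construction and tests nothing, yet its cases are counted as kept above. The matrix values largely repeat the deposited log ratio, so those cases are in effect counted more than once. A slide block was not run, because each group lies on its own slide. Cy5 was well above background for 67.3% to 77.3% of probes on an array, which limits what can be tested.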

Other observations

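The tests on the labels and on other splits were chosen after the result was seen, and that on muscle RNA before. The test on dim probes was chosen after the excess below was seen, with its limits set before the draws were made. Gene families were also compared by symbol stem after the values were seen, over 214 stems with Fisher's exact test (one-sided). A stem needed at least 10 tested genes, but Cyp2a and Cyp2c were let in below that size. Olfactory receptor genes rose more often than other genes on the arrays labelled knockout, with 47 of 529 up and 8 down (exact adjusted p = 6.88e-11), against 2.83% of all genes up. Their median change was 0.19 in Cy5 and 0.11 in the Cy3 reference, against 0.05 and 0.04 over all genes, and an artefact of the slide was not tested. The cytochrome Cyp2a genes followed, with Cyp2a4, Cyp2a5 and Cyp2a22 up of 4 (exact adjusted p = 0.0078), and near-identical Cyp2a copies can share probes. The Cyp2c stem had Cyp2c29, Cyp2c65 and Cyp2c66 up of 8 (exact adjusted p = 0.067). Genes of a family are not independent, so these p-values are too small. Cyp2a5 and Cyp2c65 were already among the largest rises, so the Cyp2a and Cyp2c p-values are no separate support.

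Dim probes and skeletal muscle RNA were weighed as technical sources of the changed genes. Over 1000 draws of other genes matched on Cy5 signal, a median of 3.4% rose and 6.42% at most, against 8.87% of 530 olfactory receptor genes (1 more under a name kept from the files), which argues against dimness as the whole cause of that excess. Of 36 muscle markers, 24 were highest on replicate 2 of both groups, a pattern shared by 4.41% of the 590 genes called higher, against 14% of all genes, while 18.5% of the 417 called lower were lowest on replicate 2 of both groups, against 18.3%. These shares decide nothing, because a call needs a small spread within groups and genes of that order have a larger one (median SD 0.296 for those highest on replicate 2 and 0.266 for those lowest, against 0.239 for all genes), so muscle RNA stays open. Other causes tied to the slide stay open, as does a true difference between genotypes, and neither was tested.

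A candidate explanation for the direction of the Pax9, Krt1 and hard keratin values is that the group labels were exchanged. As background, Pax9-deficient mouse tongue is known to gain skin-type keratins and lose hard keratins, the reverse of the direction by label here. The Pax9 probe stood 0.731 higher on the arrays labelled knockout, the 2 epidermal cornification genes called were lower there and the 4 hard keratins called were higher. These values prompted the idea and do not test it. A probe outside the deleted part need not read lower in a knockout, whichever group that is. By itself such a probe does not give a rise of 0.731. It and an exchange cannot be told apart and may both hold, because the floxed exons and the probe's place on the transcript were not used. An effect of the slide or a true effect in the labelled direction stays open too.

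The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. For changed genes 1 split, the real one, reached 1007, and the highest of the others was 0. For genes changed at least 2-fold 1 split reached 605, and the highest of the others was 0. Each other split puts arrays of both groups, and so of both slides, on each side. A group or slide difference then widens the spread within sides, which lowers the gene counts in advance. The gap from the real split could arise from a slide effect alone and decides nothing. For gene lists 6 of the 10 splits reached 9, and the highest of the others was 13, so the count of lists does not set the real split apart. The real split parts all 3 pairs of replicate numbers, as do 3 others, which gave 0 changed genes and 13, 6 and 7 lists, while the remaining splits part 1 pair.

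Krt1 had background-subtracted Cy5 signals of 257591 to 493210 on the arrays labelled wild type and 458 to 1967 on those labelled knockout, a wider gap than the ratio gives. Its Cy3 signal was 3900 to 3963 on the former and 255 to 309 on the latter, so Cy3 fell where Cy5 fell. Among keratins, Cy5 light read in Cy3 was weighed for Krt14 only, so it stays open for Krt1.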
